A study of Mus musculus with 6 samples.

How the data were processed

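Gene expression was measured by RNA sequencing of total RNA from placentas taken on day 13.5 of gestation, in 3 libraries of an abortion-prone group and 3 of a normal group. The labels give the group and a replicate number. They do not say that the replicates came from separate animals, so every p-value measures only the spread between these samples, which may be technical. The labels give no mating, strain, fetal sex or sequencing batch.

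The authors deposited 1 table with 23994 genes and a value per gene and library. The deposited values were taken as FPKM (fragments scaled to transcript length and to the size of the library), a unit inferred from the values themselves, since the header gives only library names. The submitters' processing notes name TopHat2 2.0.9 and the build mm8; the tool that turned alignments into FPKM, its gene models and its handling of strand are not given in the sources used here. The gene loci in the table were compared with GENCODE M21 on GRCm38. Of all identifiers, 99.5% were found there, and 99.97% of the matched loci overlapped the GRCm38 gene, so positions are given below as in the table and read as GRCm38. The table starts were treated as counted from 0 and shifted by 1. There are 9484 genes that share their locus with another gene, and reads of overlapping or antisense genes cannot be told apart without knowledge of the strand setting.

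FPKM values are not counts, and the depth of a library is not stated. The smallest values step with transcript length, and the value of 1 fragment gave rough estimates of depth that put normal replicate 3 highest and normal replicate 1 lowest. This estimate uses the longest GENCODE M21 transcript of each gene and is approximate, so no counting interval was computed.

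Groups were compared with limma 3.58.1 (limma-trend, R 4.3.3) on log2(FPKM + 1), over the 12365 genes with a mean of at least 1 FPKM across the 6 libraries and with no further scaling. Differences are abortion-prone minus normal on the log2(FPKM + 1) scale, which understates the change of genes with low values. Benjamini-Hochberg adjusted p-values under 0.05 passed the threshold. The counts below come from this fit of 6 libraries unless another is named. Replicate 2 of each group lies between replicates 1 and 3, as described in the results, so means and standard deviations (SD) were taken over replicates 1 and 3 (n = 2). The comparison was also fitted without both libraries numbered 2. The standard errors (SE) printed with the log2 differences of genes come from the fit of 6 libraries, which counts replicate 2 as a library of its own. Without both libraries numbered 2 they were larger, for example 0.28 instead of 0.10 for Tfpi and 0.23 instead of 0.14 for Psg22.

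Before the data were examined, 30 gene lists for placental cell types, maternal and immune cells and pathways were fixed, with Xist and the Y-linked genes as a further list given per library. The lists were tested with camera (preset correlation 0.01, two-sided) where at least 5 members were measured, which held for 25 lists, with Benjamini-Hochberg adjustment over these. Camera with an estimated correlation and fry were alternatives. fry tests whether the genes of a list move on balance one way and does not compare the list with other genes. Named genes were chosen by a rule fixed at the same time. Its first part takes the 10 largest log2 differences in each direction among genes past the threshold with no overlap between the groups and a higher group mean of at least 5 FPKM, leaving out predicted gene models. Its second part takes up to 4 members of each list with the smallest p, and its last part Xist and the Y-linked genes. Genes named outside this rule are stated as such.

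Samples with the same replicate number deviated from their group means together, with correlations across genes of 0.203, 0.234 and 0.311 for numbers 1, 2 and 3. By a rule fixed beforehand the numbers were therefore taken to pair the samples, on the evidence of the data and not of the labels. The correlations between abortion-prone replicate 2 and normal replicate 1 (0.293) and between abortion-prone replicate 1 and normal replicate 2 (0.226) were of the same size. Since replicate 2 lies between replicates 1 and 3 in each group, these correlations are not separate pieces of evidence. A fit with the replicate number as a block was run. Its values are given for part of the genes and lists described in the results whose call it changed. In other places they are given as the number of genes past the threshold in a list. Like the fit without a block, it counts replicate 2 as a library of its own. Its p-values can therefore be too small if replicate 2 repeats the others.

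Further alternatives were TMM scaling (trimmed mean of M values, computed from its formula on the FPKM values), quantile scaling, a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, a robust empirical Bayes step, no mean-variance trend, each replicate left out in turn, an added log2 difference of at least 1, and lists without shared genes. A correction for GC content and transcript length was added after the data were seen. It removed, in each library, a loess curve (span 0.3) of the deviation from the gene mean on GC content and then on log2 length of the longest GENCODE M21 transcript. Transcripts of the named genes were compared with all others using blastn 2.17.0, and a gene with another at 95% identity or more over at least 50% of its transcript is called near-identical to it. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

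The fits were tested on simulated data for 12365 genes with the observed spread. With 3 independent libraries per group and 200 changed genes, limma recovered 63% of genes changed by a log2 difference of 1 and 100% of those changed by 2. With 2 independent libraries per group it recovered 29% and 95%. With no changed genes and replicate 2 made as the mean of replicates 1 and 3, limma called 940 genes, against 5 with 3 independent libraries.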

Results

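The data describe placental tissue at day 13.5 of mouse gestation, when the labyrinth that exchanges nutrients and the hormone-secreting junctional zone are both in place. The series sets placentas of an abortion-prone group against placentas of a normal group, and its title places the comparison in a mouse model of abortion with a focus on immune-related expression. Each group has 3 libraries. The FPKM values summed to between 500073 in abortion-prone replicate 3 and 601418 in normal replicate 3, and 11836 to 12464 genes per library reached 1 FPKM. The 10 highest genes held 12.9% to 13.1% of the abortion-prone sums and 14.4% to 19.3% of the normal sums.

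Replicate 2 of each group lay between the other two libraries. Of the 8672 genes with a mean of at least 5 FPKM, 80.1% had abortion-prone replicate 2 between replicates 1 and 3, and 84.5% in the normal group. Replicate 1 or 3 lay between the other two for 7.41% to 10.7% of genes. Where replicates 1 and 3 differed at least 2-fold, replicate 2 stood at a median of 0.499 of the way from replicate 3 to replicate 1 in the abortion-prone group (289 genes) and 0.490 in the normal group (306 genes). Xist, the RNA that silences an X chromosome in female cells, and the Y-linked genes showed the same order. Abortion-prone replicate 1 had 85.3 FPKM of Xist and listed Eif2s3y, Ddx3y, Kdm5d and Uty at 0. Abortion-prone replicate 3 had 0.411 FPKM of Xist and 25.8 of Eif2s3y, 15.5 of Ddx3y, 6.35 of Kdm5d and 5.45 of Uty. Abortion-prone replicate 2 held 47.4 FPKM of Xist and 12.6 of Eif2s3y. The normal libraries had 119, 87.6 and 56.2 FPKM of Xist and no Y-linked gene above 0.0233 FPKM. Fetal sex is thus in part tied to the group in every comparison between the groups. Its role was examined only for the yolk sac list.

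**Figure D1:**
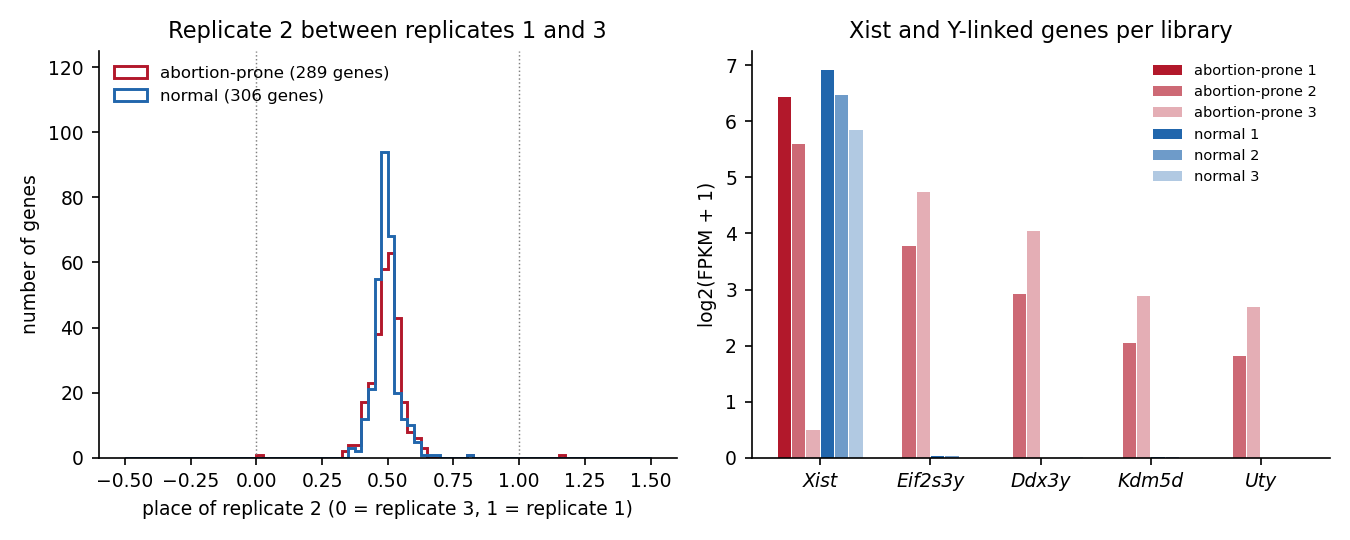
Left, histogram of the place of replicate 2 between replicate 3 (0) and replicate 1 (1) for genes with a mean of at least 5 FPKM whose replicates 1 and 3 differ at least 2-fold, by group; the medians are 0.499 (abortion-prone) and 0.490 (normal). Right, log2(FPKM + 1) of Xist and 4 Y-linked genes in each library, 1 bar per library; the Y-linked genes are present in abortion-prone replicates 2 and 3.

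Genes of the yolk sac visceral endoderm, the epithelium that makes plasma proteins before the liver does, were far higher in the abortion-prone placentas. Afp (ENSMUSG00000054932, chromosome 5, 90490737 to 90515931), the fetal plasma protein alpha-fetoprotein, stood at 1028 ± 745 FPKM against 8.21 ± 5.90 in normal placentas (SD, n = 2 each). Apoa1 (ENSMUSG00000032083, chromosome 9, 46228580 to 46230466), the main apolipoprotein of high-density lipoprotein, stood at 215.5 ± 214.6 against 1.61 ± 1.43 FPKM. Both rose with all 6 libraries, by log2 differences of 6.77 ± 0.49 (SE, limma adjusted p = 0.00114) and 6.20 ± 0.63 (adjusted p = 0.00557), and also with replicates 1 and 3 alone (adjusted p = 0.00477 and 0.0339). Of the 14 members of the fixed yolk sac list, 13 rose with 6 libraries and 14 when adjusted over the list alone, with a median log2 difference of 3.01.

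The other large increases were mostly genes of secreted plasma proteins. Ttr, a carrier of thyroid hormone and retinol-binding protein, stood at 95.3 ± 109.3 FPKM against 1.60 ± 0.779, and Apoa2 at 54.5 ± 67.8 against 0.347 ± 0.278. Spp2, a secreted phosphoprotein, Apoa4 and Apob, both apolipoproteins, Rbp4, the plasma retinol carrier, and Fgg, a fibrinogen chain, rose by log2 differences of 4.43, 4.28, 4.18, 3.96 and 3.58 (limma adjusted p from 0.00724 to 0.0122). None of these 7 genes passed with replicates 1 and 3 alone (adjusted p from 0.0815 to 0.318), while all 14 genes of the yolk sac list did when adjusted over the list alone. Afp read 501 FPKM in abortion-prone replicate 1 and 1555 in replicate 3, and Ttr 17.96 and 172.6. Camera placed the yolk sac list higher (adjusted p = 1.94e-07), and the call was lost with an estimated correlation (adjusted p = 0.660).

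The remaining gene among the 10 largest increases was Rpl26, a protein of the large ribosomal subunit, at 345 ± 67.2 against 16.5 ± 0.286 FPKM (log2 difference 4.31 ± 0.11, limma adjusted p = 1.2e-05). The largest decreases were led by processed pseudogenes, mostly of ribosomal protein genes. Rpl30-ps9 (chromosome X, 105278637 to 105278981) had 0.0913 ± 0.0247 FPKM against 24.1 ± 3.21 (log2 difference -4.52 ± 0.11, adjusted p = 1.2e-05). Rpl35a-ps6, Rpl35a-ps3, Rpl35a-ps4, Itpa-ps1, Rpl30-ps10 and Rpl35a-ps2 fell by log2 differences between -3.39 and -3.07. All of these passed with replicates 1 and 3 alone (adjusted p from 0.00109 to 0.00454). Rpl26 has 5 near-identical genes and each of the pseudogenes at least 1. The closest copy of each named Rpl35a pseudogene is another of them, at 100% identity over 100% of the transcript. Rpl30-ps9 and Rpl30-ps10 share the closest copy Gm12191. Reads could therefore be divided between copies, so these values are uncertain for the single gene, and the decreases may not be separate. Why such a division would differ between the groups was not tested, and the labels give no strain.

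The other 3 genes, all protein-coding, completed the 10 largest decreases. Psg22 (ENSMUSG00000044903, chromosome 7, 18718090 to 18727248), a glycoprotein secreted by trophoblast, had 29.9 ± 1.498 FPKM against 122.7 ± 31.2 (log2 difference -1.96 ± 0.14, limma adjusted p = 0.000930, and 0.0263 with replicates 1 and 3). AK157302 had 2.45 ± 0.293 against 12.98 ± 2.77 FPKM (adjusted p = 0.000702, and 0.0443 with replicates 1 and 3). Erdr1, at 2.31 ± 1.06 against 16.1 ± 9.88 FPKM, passed with 6 libraries (adjusted p = 0.0113) and not with replicates 1 and 3 (adjusted p = 0.216). Erdr1 has a near-identical gene.

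With 6 libraries 1828 genes were higher and 451 lower in abortion-prone placenta (limma, adjusted p under 0.05). With the block on replicate number 1159 genes were higher, 1036 of them among the 1828. With replicates 1 and 3 alone 15 genes were higher and 13 lower, all of them also called with 6 libraries, and 1094 and 215 had an unadjusted p under 0.05. Among these 28 genes, 8 of the higher and 11 of the lower were annotated as pseudogenes, and 20 had a near-identical gene. Some of the 28, such as the Rpl35a pseudogenes, are near-identical to one another, so these calls are not all separate. Outside the naming rule, and chosen after their values were seen, 3 protein-coding genes among them were Rps2, a ribosomal protein at 329.8 ± 32.9 against 84.5 ± 1.04 FPKM, Rufy4 at 12.8 ± 2.05 against 2.18 ± 0.448, and Gabra5, a receptor subunit for the transmitter GABA, at 2.53 ± 0.0159 against 0.0194 ± 0.00113. Rps2 has 27 near-identical genes, so its value is uncertain for the single gene.

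Higher genes made up 80.2% of the calls without scaling and 57.2% after TMM scaling (1309 higher, 979 lower), which moved the median log2 difference of all genes by -0.133. The groups did not overlap for 3611 genes as higher and 1428 as lower, 40.8% of the genes tested. Chance gives 10% for 3 against 3 independent libraries and 33.3% for 2 against 2, which is the nearer comparison here, since replicate 2 lies between the others. The group difference also followed base composition. Across genes, which are not independent replicates, its Spearman correlation with GC content was 0.487, and the median GC content was 54.7% for higher genes and 44.9% for lower genes. Replicate 1 minus replicate 3 followed GC content within each group as well, with Spearman correlations of 0.235 (abortion-prone) and 0.248 (normal).

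**Figure D2:**
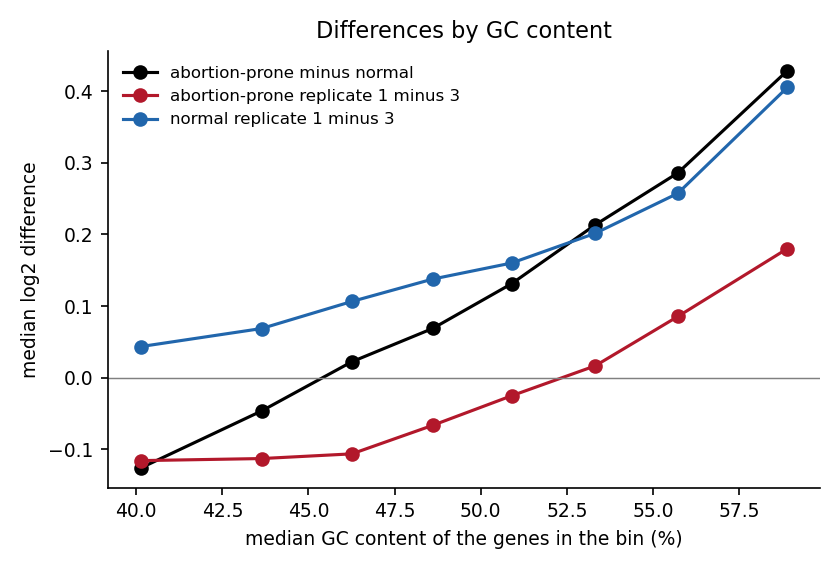
Median log2 difference in 8 bins of genes by GC content, plotted against the median GC content of the bin in percent, for abortion-prone minus normal and for replicate 1 minus replicate 3 within each group. The group difference runs from -0.13 in the lowest bin to 0.43 in the highest, and both within-group differences also increase.

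Part of the spongiotrophoblast and giant cell genes fell in the abortion-prone placentas. Of 12 spongiotrophoblast genes, 8 fell with 6 libraries (11 fell and 1 rose when adjusted over the list alone), with a median log2 difference of -0.99. Prl3c1 and Prl3a1, members of the prolactin family, had 6.93 ± 0.794 against 25.4 ± 11.1 FPKM and 0.412 ± 0.104 against 2.90 ± 0.922. Ceacam11 and Ceacam12, glycoproteins of trophoblast, had 705 ± 119.7 against 1941 ± 458 FPKM and 686 ± 45.0 against 1982 ± 669 (log2 differences -1.46 and -1.50, limma adjusted p = 0.00660 and 0.00821). Of 13 giant cell genes, 6 fell (8 when adjusted over the list alone, 2 with the block), with a median of -0.67. They included Prl7a1 at 329 ± 18.2 against 566 ± 76.7 FPKM and Prl3d1, placental lactogen, at 11.7 ± 3.20 against 23.2 ± 4.29.

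Camera placed both trophoblast lists lower, at adjusted p = 2.5e-09 for spongiotrophoblast and 1.94e-07 for giant cells, and the adjusted p was 0.660 for each with an estimated correlation. No member of either list passed with replicates 1 and 3 alone, where 6 spongiotrophoblast and 4 giant cell genes were lower at an unadjusted p under 0.05 and 6 and 0 passed as lower when adjusted over the list alone. The library means of the spongiotrophoblast list, as log2(FPKM + 1), were 8.16 to 8.21 in the abortion-prone group and 8.86 to 9.40 in the normal group. Prl3d1 has near-identical genes.

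**Figure D3:**
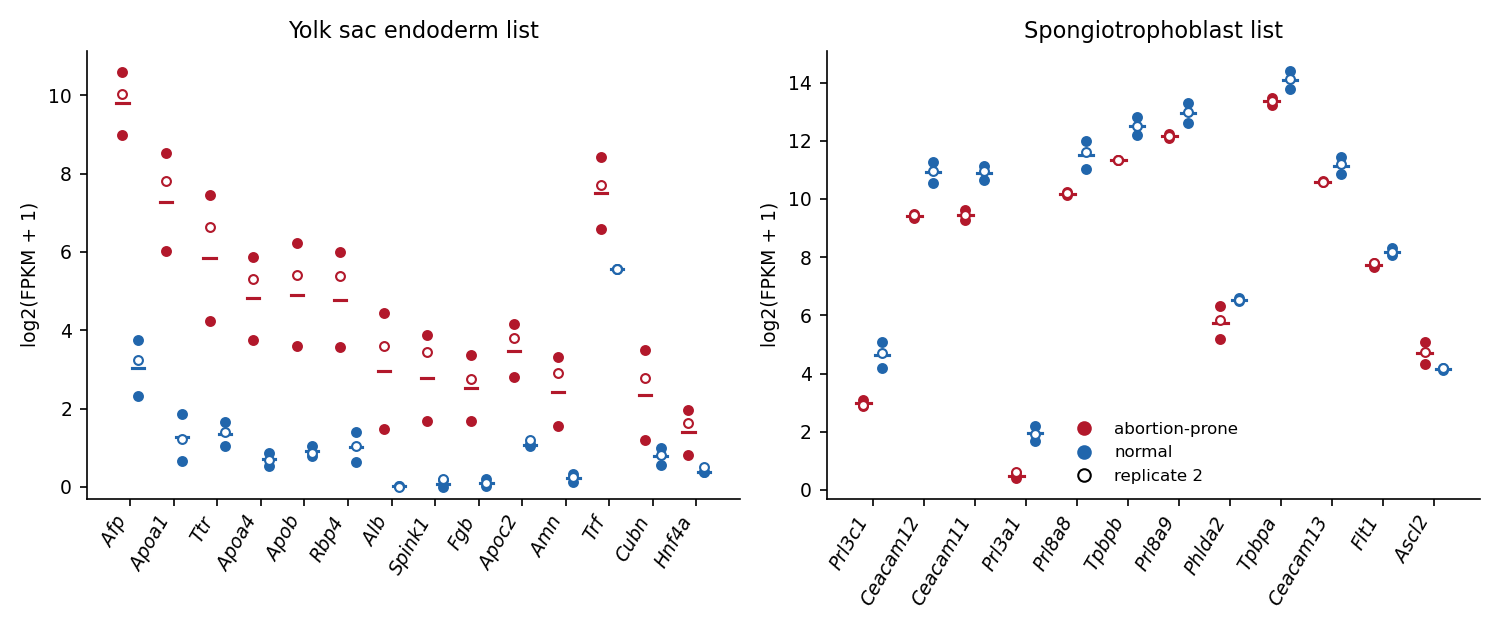
Value of each measured member of the yolk sac endoderm list (left) and the spongiotrophoblast list (right) as log2(FPKM + 1) in each library, with bars at the mean of replicates 1 and 3 and open circles for replicate 2. All 14 yolk sac genes lie higher in the abortion-prone libraries, and 11 of 12 spongiotrophoblast genes have a log2 difference below 0.

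Genes of the labyrinth and of glycogen trophoblast went partly the other way. Of 14 labyrinth and syncytiotrophoblast genes, 7 rose and 1 fell with 6 libraries (9 and 1 when adjusted over the list alone). Dlx3, a homeobox factor needed for labyrinth growth, had 42.3 ± 6.21 against 16.1 ± 5.53 FPKM (log2 difference 1.37 ± 0.18, limma adjusted p = 0.00911). Slc16a3, a lactate transporter, had 185 ± 2.68 against 131 ± 10.4 FPKM, but its log2 difference of 0.51 went to 0.11 after the correction for GC content and length. Gjb2, the gap junction protein connexin of the syncytial layers, had 382 ± 32.8 against 202 ± 58.1 FPKM and belongs also to the glycogen trophoblast list. Of 11 glycogen trophoblast genes, 5 rose (5 when adjusted over the list alone), among them Pcdh12, a protocadherin, at 42.1 ± 1.51 against 30.2 ± 0.564 FPKM (adjusted p = 0.0125, and 0.281 after the correction). Neither list passed camera (adjusted p = 0.106 and 0.430), but the labyrinth list passed as higher after quantile scaling (0.0413) and with no filter (0.0340). No labyrinth or glycogen trophoblast gene passed with replicates 1 and 3 alone. At an unadjusted p under 0.05, 6 labyrinth genes were then higher and 1 lower (3 and 1 when adjusted over the list alone), and 4 glycogen trophoblast genes were higher (0 over the list alone). The correction gave 5 and 2 higher genes in the labyrinth and glycogen lists, and the block 3 and 3.

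Among 23 imprinted genes, 5 rose and none fell with 6 libraries (5 when adjusted over the list alone), and 9 were higher and 1 lower at an unadjusted p under 0.05. Snrpn, expressed from the paternal copy, had 28.3 ± 4.11 against 13.7 ± 0.993 FPKM (log2 difference 0.99 ± 0.10, limma adjusted p = 0.00581). Dlk1, another paternally expressed gene, had 65.1 ± 5.28 against 36.3 ± 12.3 FPKM, and its adjusted p of 0.0215 went to 0.0508 with the block, which left only Snrpn of the imprinted genes past the threshold. With replicates 1 and 3 alone no imprinted gene passed (Snrpn adjusted p = 0.279), and 3 were higher at an unadjusted p under 0.05. The imprinted list did not pass camera (adjusted p = 0.118), but passed as higher with no filter (0.0233) and without abortion-prone replicate 1 (0.0364). Of 15 decidua genes, 3 rose and 1 fell (the same numbers when adjusted over the list alone). Igfbp1, an insulin-like growth factor carrier, had 2.13 ± 0.0862 against 0.573 ± 0.152 FPKM, and Prl3c1, which this list shares with the spongiotrophoblast list, was the gene that fell. The decidua list had a median of -0.41 and an adjusted p of 0.211, and it passed as lower with the block (adjusted p = 0.0157) and without abortion-prone replicate 1 (adjusted p = 0.0316). Without abortion-prone replicate 3 the decidua median was 0.24.

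Of 9 erythroid genes, 4 fell with 6 libraries (7 when adjusted over the list alone), with a median log2 difference of -1.12. They were the embryonic globins Hbb-bh1, at 30.5 ± 16.4 against 117 ± 69.0 FPKM, Hba-x, at 92.6 ± 32.5 against 293 ± 183, and Hbb-y, at 2814 ± 971 against 7144 ± 3949, and the anion exchanger Slc4a1, at 2.12 ± 1.47 against 7.22 ± 2.31. Camera placed the list lower (adjusted p = 6.53e-05), and the call was lost with an estimated correlation (adjusted p = 0.660). With the block 6 were lower. No erythroid gene passed with replicates 1 and 3 alone, where 4 were lower at an unadjusted p under 0.05 and 3 when adjusted over the list alone.

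Extracellular matrix genes were higher in part. Of 22 measured, 9 rose with 6 libraries (12 when adjusted over the list alone), led by Col1a1, a chain of fibrillar collagen, at 21.1 ± 11.8 against 5.11 ± 2.24 FPKM (log2 difference 1.84 ± 0.32, limma adjusted p = 0.0164). Col6a2 had 1.82 ± 0.883 against 0.532 ± 0.187 FPKM, and its adjusted p of 0.0225 went to 0.0545 with the block. The list missed the camera threshold with 6 libraries (adjusted p = 0.0945) and passed with replicates 1 and 3 alone (adjusted p = 0.0356, and at least 0.658 for every tested list with an estimated correlation). It also passed after TMM scaling (0.0372), after quantile scaling (0.0269) and with no filter (0.0262). Of the 22 genes, 6 were higher with the block, 1 after the correction for GC content and length, and none with replicates 1 and 3 alone, where 8 were higher at an unadjusted p under 0.05.

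Vessel and muscle genes passed in part. Of 18 angiogenesis genes, 5 rose and 1 fell (the same numbers when adjusted over the list alone), 4 and 2 with the block, and after the correction 1 was higher and 2 lower. Pdgfb, a growth factor for pericytes, had 14.7 ± 3.72 against 5.18 ± 0.664 FPKM (log2 difference 1.36 ± 0.15, limma adjusted p = 0.00636), while Flt1, a receptor for vascular endothelial growth factor that is also made by spongiotrophoblast, had 212 ± 11.7 against 293 ± 33.2. Of 14 endothelial genes, Sox18, an endothelial transcription factor, rose (0 genes passed when adjusted over the list alone), at 4.75 ± 0.801 against 3.18 ± 0.227 FPKM, and its adjusted p of 0.0377 went to 0.0827 with the block. After the correction for GC content and length its log2 difference went from 0.45 to 0.0088 (adjusted p = 0.959), and the endothelial list had 0 higher and 2 lower genes. Plvap, at 33.9 ± 1.35 against 29.3 ± 1.16 FPKM, did not pass (adjusted p = 0.0941). Of 8 smooth muscle genes, 4 rose (4 when adjusted over the list alone), including Lmod1 at 2.42 ± 0.464 against 0.811 ± 0.445 FPKM and Smtn at 46.6 ± 6.69 against 28.6 ± 7.51. The block left Lmod1 and Smtn past the threshold but not Mylk and Actg2 (adjusted p = 0.0999 and 0.0618). The correction left 2 higher smooth muscle genes and took Smtn from a log2 difference of 0.69 to 0.18 (adjusted p = 0.112). Camera gave adjusted p = 0.331, 0.242 and 0.184 for the angiogenesis, endothelium and smooth muscle lists. No gene of these lists passed with replicates 1 and 3 alone, where 3, 0 and 3 were higher at an unadjusted p under 0.05.

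Among immune cell genes, calls lay in the neutrophil and dendritic cell lists. None of 8 uterine natural killer cell genes passed limma, adjusted over the list alone or at an unadjusted p under 0.05. Prf1, the pore-forming protein of cytotoxic granules, had 8.19 ± 9.70 against 21.2 ± 15.3 FPKM (adjusted p = 0.166, and 0.0365 with the block), and Gzme, a granzyme, 57.5 ± 66.3 against 132 ± 89.8. The list means were 6.37 and 3.16 in abortion-prone replicates 1 and 3 and 7.06 and 5.62 in normal replicates 1 and 3. The ranges of the groups overlapped, while each abortion-prone library was below the normal library of the same number (5.597 against 6.51 for replicate 2). Camera placed the list lower (median -1.53, adjusted p = 0.00754, and 5.22e-05 with the block). The natural killer cell call rested on abortion-prone replicate 3, without which the median was -0.43 (adjusted p = 0.0776). The adjusted p was 0.660 with an estimated correlation, 0.0598 after the correction for GC content and length (median -1.56), and 0.0519 after TMM scaling (median -1.68). With the correction it passed when the block was added (0.00189) and with replicates 1 and 3 alone (0.00404). Decidua genes, of another maternal cell type, were lowest in the same library, with list means of 4.53, 3.96 and 2.46 in abortion-prone replicates 1 to 3 and 4.64, 4.17 and 3.36 in the normal ones. Xist, which female maternal cells also express, was at 0.411 FPKM in abortion-prone replicate 3. It was at 85.3 in abortion-prone replicate 1 and at 56.2 to 119 in the normal libraries. How much maternal tissue each library held was not tested.

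None of 12 macrophage and monocyte genes passed limma, adjusted over the list alone or at an unadjusted p under 0.05. Ly6c2, a monocyte surface protein, had 26.7 ± 34.0 against 62.1 ± 41.0 FPKM, Csf1r, the receptor for colony-stimulating factor, 119.7 ± 16.7 against 136 ± 15.2, and C1qa, a complement chain made by macrophages, 2.15 ± 0.399 against 1.68 ± 0.0496. After the correction for GC content and length Csf1r alone of this list passed, as lower (log2 difference -0.16 before and -0.50 after, limma adjusted p = 0.0223). The list had an adjusted p of 0.103 in camera and passed as lower with the block (adjusted p = 0.0357) and without abortion-prone replicate 1 (0.0167). Of 4 measured neutrophil genes, Cxcr2, a chemokine receptor, and S100a9, a calcium-binding protein of neutrophils, fell (2 when adjusted over the list alone), at 19.1 ± 1.56 against 26.4 ± 1.63 FPKM and 3.82 ± 1.93 against 7.50 ± 1.18. S100a9 no longer passed after the correction (adjusted p = 0.145). Of 4 measured dendritic cell genes, 2 rose and 1 fell (the same numbers when adjusted over the list alone, 1 and 0 with the block). Batf3, a transcription factor of dendritic cells, had 37.8 ± 7.77 against 20.4 ± 0.106 FPKM (adjusted p = 0.00958), and Zbtb46 3.20 ± 0.464 against 1.95 ± 0.528 (adjusted p = 0.0330, and 0.0788 with the block). The correction took Batf3 from a log2 difference of 0.86 to 0.47, and it still passed (limma adjusted p = 0.00934). Flt3, a receptor of dendritic cell precursors, had 7.36 ± 4.77 against 7.99 ± 0.544 FPKM. Only Itk and Lck of 15 T cell genes reached the mean of 1 FPKM, at 2.33 ± 0.408 against 2.505 ± 0.285 and 2.29 ± 0.258 against 1.93 ± 0.0688, and no B cell gene did. These short lists were tested with camera only with no filter on low values, where the neutrophil list passed as lower (13 genes, median -0.19, adjusted p = 0.000625) and the T cell, B cell, dendritic cell and class II lists did not (adjusted p from 0.181 to 0.463). Camera with an estimated correlation was not run on them.

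Genes of antigen presentation and immune signalling gave few calls. Of 14 genes of the class I pathway, Tapbp, a peptide-loading chaperone, rose and H2-T24 fell with 6 libraries (0 genes when adjusted over the list alone). Tapbp had 80.2 ± 4.77 against 64.7 ± 6.14 FPKM and H2-T24 3.37 ± 0.314 against 4.65 ± 0.125, and neither passed with the block (adjusted p = 0.0634 and 0.0824). After the correction Tapbp had a log2 difference of -0.04 (adjusted p = 0.677). Tap1, a peptide transporter, had 9.50 ± 3.25 against 7.58 ± 0.0497 FPKM (adjusted p = 0.263). None of 3 class II genes passed limma, adjusted over the list alone or at an unadjusted p under 0.05. H2-DMa had 2.40 ± 0.591 against 1.59 ± 0.782 FPKM, Ctss 4.42 ± 4.30 against 3.96 ± 1.45, and Cd74, the invariant chain, 1.52 ± 1.01 against 1.42 ± 0.0794. Of 21 interferon response genes, Oas1a, an oligoadenylate synthetase with a near-identical gene, rose at 22.5 ± 0.363 against 13.6 ± 0.293 FPKM (1 gene when adjusted over the list alone, adjusted p = 0.00717 over all genes). Ifit1 did not pass, at 2.68 ± 0.705 against 3.98 ± 0.508 FPKM.

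Of 10 cytokine and chemokine genes, Tgfb1, a cytokine that restrains T cells, rose at 8.37 ± 3.07 against 3.49 ± 1.59 FPKM (log2 difference 1.04 ± 0.24, limma adjusted p = 0.0304, 1 gene when adjusted over the list alone). Cxcl12, Il1b and Il1a did not pass, with log2 differences of -0.64, -0.46 and -0.51. After the correction for GC content and length Cxcl12 passed as lower (log2 difference -0.88, limma adjusted p = 0.0260), and Il1b and Il1a did not (0.199 and 0.295). Of 9 immune tolerance genes, Tgfb1 rose and Nt5e, the enzyme that makes adenosine from AMP, fell at 11.6 ± 0.808 against 18.7 ± 2.09 FPKM (the same 2 genes in number when adjusted over the list alone). Camera gave adjusted p = 0.242, 0.0945, 0.143 and 0.0984 for the class I, interferon, cytokine and tolerance lists. With the block the interferon and tolerance lists passed as lower (adjusted p = 0.0357 and 0.0463), the tolerance list also without shared genes (0.0297). Without abortion-prone replicate 1 the class I, interferon and tolerance lists passed as lower (adjusted p = 0.0167, 0.0167 and 0.0391), while without abortion-prone replicate 3 the class I median went from -0.08 to 0.36. Each of the 25 lists tested had an adjusted p of at least 0.660 in camera with an estimated correlation. No gene of the immune lists passed with replicates 1 and 3 alone, where at most 1 gene of a list in each direction had an unadjusted p under 0.05 and 1 dendritic cell gene passed when adjusted over its list alone.

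Clotting genes moved both ways. Of 22 complement and coagulation genes, 6 rose and 2 fell (8 and 2 when adjusted over the list alone), with camera at adjusted p = 0.962. The fibrinogen chains Fgg and Fga, at 14.7 ± 12.1 against 0.183 ± 0.226 and 12.9 ± 11.6 against 0.110 ± 0.0420 FPKM, and Proc, the anticoagulant protein C, at 5.64 ± 0.589 against 2.60 ± 0.321, rose. Fgg and Fga read 6.15 and 4.66 FPKM in abortion-prone replicate 1 and 23.3 and 21.1 in replicate 3, the order also seen for Afp and Ttr. Proc, at 6.06 and 5.23, did not show it. A further fibrinogen chain, Fgb, is in both this list and the yolk sac list, so the fibrinogen increases may not be separate from the yolk sac ones. Tfpi, the inhibitor of the tissue factor pathway, fell at 782 ± 19.9 against 1638 ± 89.0 FPKM (log2 difference -1.07 ± 0.10, limma adjusted p = 0.00397). Of 15 steroid and cholesterol genes, 2 rose and 3 fell (the same numbers when adjusted over the list alone). Star, which carries cholesterol into mitochondria, had 12.6 ± 1.51 against 25.3 ± 3.43 FPKM and Cyp17a1, a steroid hydroxylase, 19.8 ± 0.156 against 33.4 ± 3.37. Hsd11b2, which inactivates glucocorticoid, had 71.2 ± 10.9 against 35.6 ± 7.63 FPKM and rose. Camera gave adjusted p = 0.128 for this list, and 0.0328, as lower, with the block, which gave 1 higher and 5 lower steroid genes and 4 higher and 2 lower clotting genes. No gene of the complement or steroid lists passed with replicates 1 and 3 alone (Tfpi adjusted p = 0.347, Star 0.319). When adjusted over each list alone, 5 were then higher and 1 lower in the complement list, and 1 and 3 in the steroid list.

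Stress and metabolic genes gave scattered calls. Of 13 immediate early genes, 4 rose (5 when adjusted over the list alone), led by Jun at 30.8 ± 8.05 against 16.2 ± 3.68 FPKM and Ier2 at 12.999 ± 4.92 against 6.67 ± 0.567. The correction for GC content and length left 2 higher immediate early genes. It took the list median from 0.46 to 0.18 and Ier2 from a log2 difference of 0.86 to 0.43. Camera gave adjusted p = 0.0945 for the list, and 0.0136, as higher, with the block. It also passed after quantile scaling (0.0394), without abortion-prone replicate 3 (0.00629) and with the correction and the block together (0.0325). Of 18 genes of the unfolded protein response and heat shock, 4 rose and 2 fell (5 and 5 when adjusted over the list alone). Hsp90b1, a chaperone of the endoplasmic reticulum, had 407 ± 67.5 against 635 ± 8.25 FPKM and fell, and Sesn2, a stress-induced gene, had 11.2 ± 0.258 against 6.83 ± 1.58 and rose. The correction took Sesn2 from a log2 difference of 0.69 to 0.23 (adjusted p = 0.0827) and left 1 higher and 6 lower genes in the list. The list had a median of 0.0049 and a mean of 0.09, and camera placed it lower without passing (adjusted p = 0.211). Of 20 hypoxia and glycolysis genes, Hk1, a hexokinase, and Pfkl, a phosphofructokinase, rose (0 genes when adjusted over the list alone), at 18.1 ± 3.11 against 10.7 ± 3.18 and 16.6 ± 2.49 against 10.6 ± 3.40 FPKM. After the correction for GC content and length neither passed (log2 differences 0.33 and 0.24, adjusted p = 0.0695 and 0.134), and the list had 0 higher and 3 lower genes. Of 26 oxidative phosphorylation genes, Sdhc, a subunit of succinate dehydrogenase, rose at 33.5 ± 6.84 against 19.6 ± 1.13 FPKM (1 gene when adjusted over the list alone). Camera gave adjusted p = 0.566 and 0.106 for the hypoxia and oxidative phosphorylation lists. The oxidative phosphorylation list passed as lower without normal replicate 1 (median -0.11, adjusted p = 0.00290) and without abortion-prone replicate 1 (0.0485), and had a median of 0.10 without normal replicate 3 (0.764). With the block 7 immediate early genes were higher, and 3 higher and 1 lower of the unfolded protein list. No gene of these stress and metabolic lists passed with replicates 1 and 3 alone, also when adjusted over each list alone (Jun adjusted p = 0.363, Hsp90b1 0.417), and at an unadjusted p under 0.05 2 immediate early, 3 unfolded protein, 1 hypoxia and 1 oxidative phosphorylation genes were higher and 1 unfolded protein gene lower.

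None of 22 cell cycle genes passed limma, also when adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Pcna, the sliding clamp of DNA replication, had 52.1 ± 8.72 against 68.1 ± 4.22 FPKM (adjusted p = 0.0533), and Ccne1, a cyclin of S phase entry, 10.7 ± 4.70 against 16.3 ± 1.16. Pcna has a near-identical pseudogene. Camera placed the list lower (median -0.07, adjusted p = 0.0302). The adjusted p was 0.667 with an estimated correlation and 0.0892 after the correction for GC content and length (median -0.20), and 0.0423 after the correction with replicates 1 and 3 alone. The cell cycle call was also lost without abortion-prone replicate 1 (median 0.11, adjusted p = 0.486), without normal replicate 1 (0.0527), with a mean of at least 5 FPKM (0.0576) and with no filter (0.0691).

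Across the 25 lists tested, 6 passed camera with 6 libraries, 12 with the block, 7 with replicates 1 and 3 alone, and 0 with an estimated correlation, where no list had an unadjusted p under 0.05. fry gave 3 lists (spongiotrophoblast, labyrinth and yolk sac endoderm, lowest adjusted p = 0.0476), and none with replicates 1 and 3 alone (lowest adjusted p = 0.759).

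**Figure D4:**
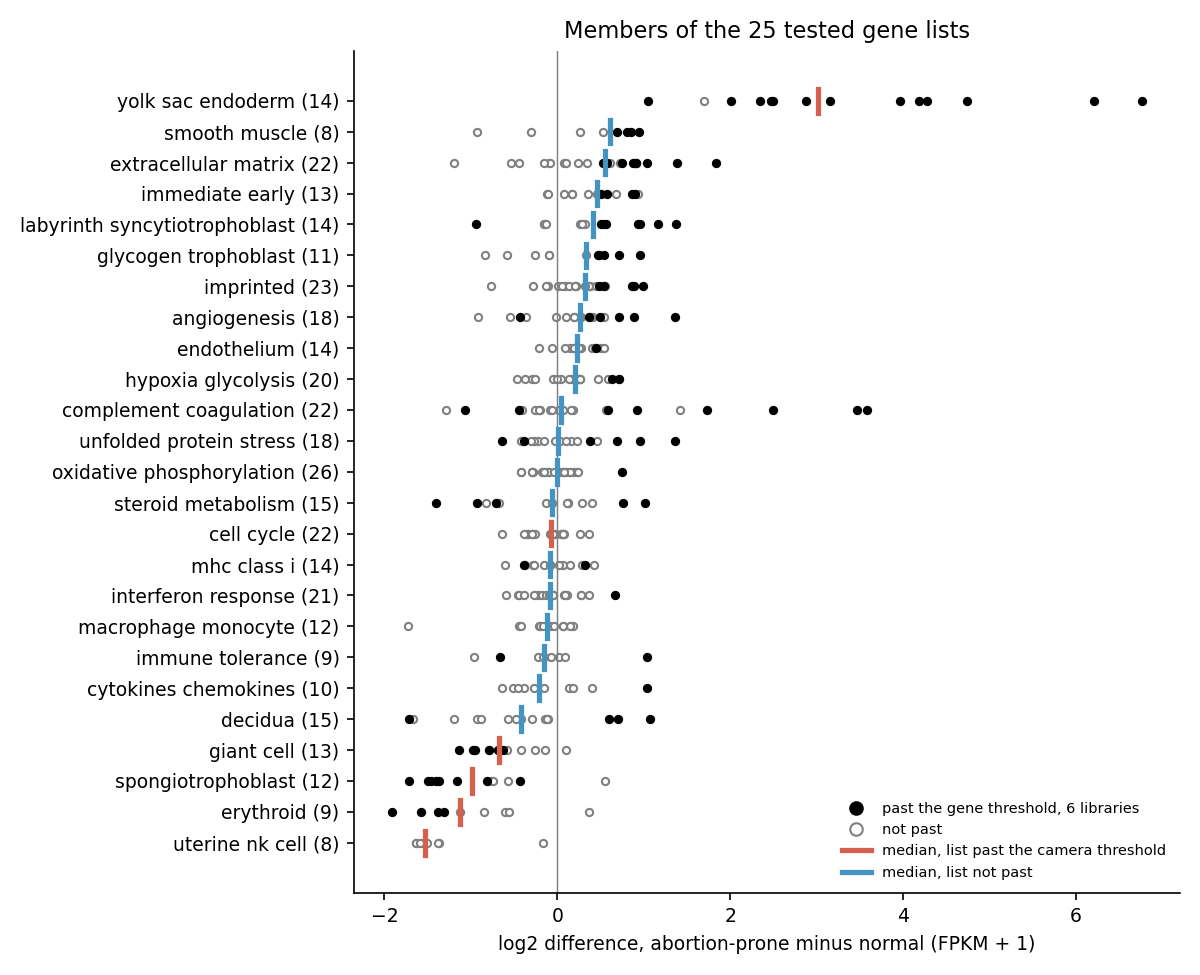
Log2 difference (abortion-prone minus normal, 6 libraries) of every measured member of the 25 tested lists, with the number of members in brackets; filled points passed the gene threshold and the vertical bar is the list median. The yolk sac endoderm list has a median of 3.01, and the 5 lists that camera placed lower have medians from -1.53 to -0.07.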

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

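The settings with replicates 1 and 3 only and those with a correction for GC content and length were chosen after the data were seen. Against 1828 higher and 451 lower genes with 6 libraries, replicates 1 and 3 gave 15 and 13, the replicate block 1159 and 331, the correction 1126 and 887, the correction with replicate block 898 and 852, and the correction with replicates 1 and 3 gave 13 and 15. An added log2 difference of at least 1 left 228 and 71, TMM scaling gave 1309 and 979, and quantile scaling 1393 and 1015. The other settings (pseudocount, filters, robust step, no trend) stayed within 1.5 times of both counts. Leaving out 1 library gave 24 to 2455 higher and 22 to 456 lower genes. Without abortion-prone replicate 2 there were 24 and 24, and without normal replicate 2 there were 24 and 22, while leaving out another library gave at least 966 and 271 (without normal replicate 3, 958 and 242 of them among the calls with 6 libraries), and 286 lower genes without abortion-prone replicate 1. The number of libraries alone does not account for these falls, since leaving out a replicate 1 or 3 removes as many libraries as leaving out a replicate 2. In simulated data without changed genes, replicate 2 made as the mean of the others gave 940 false calls. With 2 independent libraries per group instead of 3, the simulated fits recovered 29% instead of 63% of genes changed by a log2 difference of 1 and 95% instead of 100% by 2, so power was also lost, and how many calls with 6 libraries are false is not known. Depth is known only as an estimate, so no limit from counting was computed.

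Of 25 lists, 6 passed camera, 12 with the replicate block, 3 with fry and 0 with an estimated correlation. Leaving out 1 library gave 6 to 12 lists, with 12 without abortion-prone replicate 1. The cause of the additional lists was not tested. The replicate block ended the call of 17 of the 126 named genes and added 4, and the correction ended 21 and added 5. With replicates 1 and 3 only, 76 named genes no longer passed.

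Of the named genes, 118 kept their direction in every setting run, and 8 did not. With the correction alone, with the block and with replicates 1 and 3 only, Plvap had log2 differences of -0.24, -0.24 and -0.25, C1qa -0.16, -0.16 and -0.13, Tapbp -0.039, -0.039 and -0.055, Tap1 -0.067, -0.067 and -0.098, gene Lck -0.15, -0.15 and -0.0441, and Cd74 -0.25, -0.25 and -0.26. Lck was also at -0.0488 with TMM and -0.0476 with quantile scaling, and ranged from -0.00971 (without abortion-prone replicate 3) to 0.11 with 1 library left out. The gene Cd74 was also at -0.0876 with TMM, -0.0634 with quantile scaling, -0.0362 with a pseudocount of 0.1 and -0.00321 with replicates 1 and 3 only, and ranged from -0.19 to 0.23 with 1 library left out, below 0 without abortion-prone replicate 1 or 2 (-0.19 and -0.0298) or normal replicate 1 (-0.0272). Ctss was at 0.055 with the correction, with and without the block, and ranged from -0.41 to 0.51 with 1 library left out, above 0 without normal replicate 2 (0.0233), normal replicate 1 (0.11) or abortion-prone replicate 3 (0.51). Flt3 ranged from -0.44 to 0.18 (without abortion-prone replicate 1). Of these genes only Tapbp had passed with 6 libraries, and the cause of the reversals was not tested.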

Other observations

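The tests of replicate 2, of fetal sex for the yolk sac genes, and of the GC trend and transcript length behind the excess of higher genes were chosen only after those results were seen, as were the gene families described next.

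In 4 placental gene families a part of the members passed as lower in the abortion-prone libraries and none as higher. Of 13 measured pregnancy-specific glycoprotein (Psg) genes, 11 passed limma as lower with 6 libraries, and Psg22 alone passed with replicates 1 and 3; the log2 differences ran from -1.96 to -0.43 with a median of -1.12. Of 23 placental prolactin family genes 9 passed as lower (median -0.79), of 12 Ceacam genes 6 (median -0.80), and of 6 placental cathepsins 4 (median -0.68). Members of the prolactin and Ceacam families are also in the spongiotrophoblast and giant cell lists, so these counts in part repeat the values given for those lists. All members of these 4 families had log2 differences below 0, and the medians after TMM scaling were -1.28, -0.94, -0.92 and -0.83. Near-identical genes exist for 4 of the Psg and 5 of the prolactin family genes, so values of single members are uncertain. Camera on the families, which were picked from these data, was past 0.05 in all 4 with the preset correlation and in none with an estimated one (adjusted p from 0.141 to 0.257). Of 5 Serpina genes, which encode plasma protease inhibitors, 4 passed as higher (median 2.24), and of 18 collagen genes 11 passed as higher with a median of 0.72 that went to 0.24 after the correction for GC content and length. With replicates 1 and 3 alone no prolactin family, Ceacam, cathepsin, Serpina or collagen gene passed.

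One hypothesis, with its test written beforehand, was that the lower Psg values may reflect fewer spongiotrophoblast reads in the abortion-prone libraries, since Psg genes are expressed in that layer. It required the Psg median to lie within 0.5 of the median of the spongiotrophoblast list, and the difference between the medians was -0.13 (SE 0.28). The SE was taken across genes, which are not independent replicates. The rule is not specific to spongiotrophoblast, since the erythroid list, with a median of -1.12, would also meet it. The test therefore cannot tell a shared spongiotrophoblast decrease from other decreases of similar size. The values thus allow one common decrease, and do not say whether it comes from tissue composition, dissection or expression per cell.

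Replicate 2 of each group lay between replicates 1 and 3. If it were an independently sequenced library, of an intermediate animal or of pooled RNA, low genes would be sampled anew, and genes at 0 in replicates 1 and 3 would often appear in it. In the normal group 0.185% of such genes (3 of 1622) were above 0 in replicate 2 and in the abortion-prone group 0.468% (8 of 1708), against 25.4% to 30.0% for replicates 1 and 3 in the same count. This argues against independent sequencing and is consistent with replicate 2 holding reads of replicates 1 and 3. How the reads came to be combined was not tested.

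The higher yolk sac endoderm genes may come from visceral endoderm tissue in the abortion-prone libraries. A second list of 28 endoderm genes, written before its test and with 1 gene in any fixed list, had 20 measured members, of which 18 had log2 differences above 0, with a median of 0.67 (SE 0.20) against the 0.5 required. The median passed 0.5 by less than its SE, which was taken across genes that are not independent. It lay below the 3.01 of the first list. With 6 libraries 10 of the 20 passed limma as higher and 0 as lower. With replicates 1 and 3 alone the lowest adjusted p was 0.272. Ahsg had 8.72 ± 10.8 against 0.340 ± 0.176 FPKM (limma adjusted p = 0.0592 with 6 libraries). Ctsh had 25.8 ± 3.88 against 10.3 ± 3.37 FPKM (n = 2 each). Its limma adjusted p was 0.00939 with 6 libraries and 0.272 with replicates 1 and 3 alone. Of the 20 genes, 7 were already at 5 FPKM or more in normal placenta. Fetal sex as the sole cause is argued against, since the first list had a median log2 ratio of 1.66 in abortion-prone replicate 1, which listed Y-linked genes at 0, to normal replicates 1 and 3. The ratio was 4.10 in abortion-prone replicate 3, which had Y-linked reads, and each gene was 2.85 to 11.5 times as high there as in replicate 1, so a partial role of sex stays open. GC content is argued against, since 103% of the list median was kept after the correction. Attached yolk sac, fetal liver RNA and a change of expression in the abortion-prone group stay open, and the design does not separate them.

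The excess of higher over lower genes may follow a GC trend between libraries. Such a trend was present within groups, where it cannot come from the group, with a smaller Spearman correlation of 0.235 across genes. The numbers of calls do not settle it: the correction gave 1126 and 887, but it also centres each library, and TMM scaling, which has no GC term, gave 1309 and 979. Transcript length had a correlation of 0.0949 with the group difference, which argues against a length trend in that difference. This value is the balance of trends of opposite sign, -0.287 for abortion-prone minus normal replicate 1 and 0.375 for replicate 3, so a length effect within single libraries is not excluded. A biological part of the GC trend, including one tied to the abortion-prone group, stays open.

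The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1828 higher and 451 lower genes with limma, the largest in 1 of the 10 splits for each direction, and the highest other value was 0, with 0 to 1117 genes at an unadjusted p under 0.05. Only the real split keeps every library with the others of its group. All other splits part a replicate 2 from a library whose reads it may hold. They also set the group difference within their arms, so the 0 calls there cannot weigh the role of chance. For gene lists 7 of the 10 splits gave at least the 6 lists of the real one, and the highest other split gave 13. The 3 splits that set abortion-prone replicates 2 and 3 with 1 normal library against the rest gave 11 to 13 lists, which points to a structure of the samples other than the groups. Among the 4 splits that part every same-numbered pair, the 3 others gave 3 to 12 lists and no gene.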
